A study of Mus musculus with 2 samples.

How the data were processed

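Small RNA libraries (microRNA-seq) from the gastrocnemius, a hindlimb calf muscle, were analysed for 2 male B6CASTF1/J mice of 10 days of age, the F1 cross of C57BL/6J and CAST/EiJ. The labels number the samples as biological replicates 1 and 2 and as separately numbered animals, and they give both the same donor entry. They record a size range below 30 without a unit. The series holds 1 group, so no comparison between conditions was possible.

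The authors deposited 1 table of raw read counts per library, with 2202 miRNA genes and 4 summary rows for reads that were unmapped, matched several genomic places, lay in no gene or lay in several genes. Per the metadata text deposited beside each table, the assembly was mm10 and the annotation was GENCODE release M21. The aligner, the counting program and their versions are not given in the sources used here. Each table has 3 count columns, which hold reads counted without regard to strand and reads on each strand. The tables have no header that names the strands. The column was therefore chosen by a rule set before the data were examined, which took the stranded column with the larger total if it was at least 5 times the other. The ratio was 5.53. The chosen column counts reads in the sense of the miRNA genes, and its ambiguous row holds 0 reads. All 2202 gene identifiers were found in the M21 annotation, which supplied symbols, coordinates (1-based, mm10) and the host genes on the same strand.

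This counting has 2 consequences for the values. Reads that match several places are in no gene, so a miRNA whose mature sequence occurs in several genomic copies can be undercounted, and the longest stretch of hairpin that each gene shares with another annotated miRNA gene was computed from the M21 transcript sequences to mark genes where this is possible. Stretches of 14 to 60 nt were searched, and one of at least 20 nt was called shared. The search covered annotated miRNA genes only and did not know which part of a hairpin is the mature arm. Counts are per hairpin gene, so the arms cannot be told apart. In addition, 64 genes overlap a miRNA gene on the opposite strand, and in the unstranded column their reads are ambiguous.

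The summary rows were left out of the library totals. They held 58.7% of all reads in replicate 1 and 60.7% in replicate 2. Levels are counts per 1000000 counts assigned to miRNA genes (CPM), given as mean ± SD over the 2 libraries. A count of 0 allows up to 3 counts, which is 0.75 CPM in replicate 1 and 0.593 CPM in replicate 2. Genes with at least 10 counts in both libraries were called detected. Agreement was measured across genes with a mean of at least 10 counts, on log2(CPM + 1). The spread was also estimated as the biological coefficient of variation, the square root of the edgeR common dispersion with an intercept-only design. Differences between the 2 libraries were tested per gene with a two-sided exact binomial test on the counts, given TMM-scaled library totals, with Benjamini-Hochberg adjustment at 0.05. This test measures counting error only. It compares these 2 libraries, not conditions. Reads carry no molecular identifiers in these tables, so intervals and limits of detection also cover counting error only. Intervals are exact (Clopper-Pearson) at 95%.

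The named genes are the 20 with the highest mean CPM, the 5 with the largest ratio in each direction among genes past the test with a mean CPM of at least 100, and up to 4 leading members of each of 18 lists, with any member at 0 counts. The lists and the rule were fixed together with the column rule. Other genes are named where a paragraph says that they were chosen after their values were seen. The lists hold muscle miRNAs, the let-7 family, the Mir17-92 and paralogous clusters, the Mir29 and Mir30 families, the Dlk1-Dio3 imprinted cluster, other imprinted loci, the X-linked Mir322 cluster, and markers of fibroblasts, smooth muscle, endothelium, erythroid cells, leukocytes, neural and Schwann cells, brown adipocytes, epithelia, liver with gut and pancreas, and embryonic stem cells.

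The alternatives were the unstranded column, DESeq2 size factors or plain totals in place of TMM, other count minimums and pseudocounts, all reads as the denominator, each library alone, and a negative binomial exact test. The binomial test was tested on simulated Poisson counts of the 2 libraries. Among 331 simulated genes, 24 of 33 genes changed 1.5-fold, 34 of 37 changed 2-fold and 34 of 34 changed 4-fold were called with the right sign, and 8 of 227 unchanged genes were called. These Poisson counts held counting error only, so the rates do not carry over to the real libraries, which also vary beyond it. A simulated coefficient of variation of 0.14 was recovered as 0.149. The software was Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and numpy 2.4.6, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.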

Results

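The miRNA content of the gastrocnemius was profiled in 2 male B6CASTF1/J mice at 10 days after birth. The labels name 1 group and no treatment, so the data answer which miRNA genes the young muscle contains, at what level, and how closely 2 samples of the same kind match. Replicate 1 held 9678334 reads, of which 3999172 were assigned to miRNA genes. Replicate 2 held 12889382 reads, of which 5062714 were assigned. The assigned share was 40.3% ± 1.4 (SD, n = 2). A larger share, 47.5% ± 0.71, matched several genomic places and was counted for no gene. That share was 47.0% in replicate 1 (exact interval 46.97 to 47.03) and 48.0% in replicate 2 (exact interval 47.97 to 48.02).

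**Figure D1:**
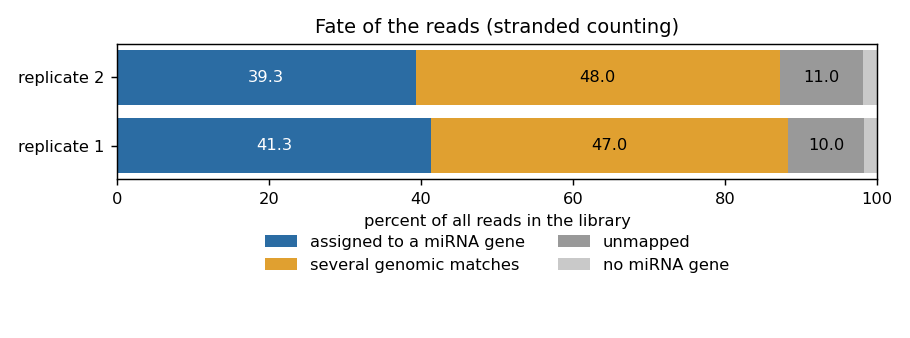
Percent of all reads per library, by fate, for replicates 1 and 2. Reads with several genomic matches took 47.0% and 48.0% of the libraries, more than the 41.3% and 39.3% assigned to miRNA genes.

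A small number of miRNA genes held most of the assigned counts, among them genes of the imprinted Dlk1-Dio3 cluster and the let-7 family, Mir206, Mir378a and Mir126a. Reads that matched several places have no part in this ranking. The 10 most abundant genes took 61.8% ± 0.23 of the assigned counts. The highest level was that of Mir127 (chromosome 12, 109592846 to 109592915, plus strand, no host gene on that strand), at 96935 ± 1871 CPM. Mir206 (chromosome 1, 20679010 to 20679082, in an exon of the long non-coding RNA Gm28653), a miRNA known to be specific to skeletal muscle, followed at 94022 ± 9301 CPM. Mir378a (chromosome 18, 61397835 to 61397900, in an intron of Ppargc1b, a transcriptional coactivator of mitochondrial genes) stood at 89927 ± 6259 CPM. Mir127 and Mir206 exchanged the first and second ranks between the libraries, and their means differed by less than the SD of Mir206.

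The next levels belonged to members of let-7, to another gene of the imprinted cluster and to an endothelial miRNA. Mirlet7i (chromosome 10, 122985640 to 122985724, no host gene on its strand) reached 66147 ± 458 CPM. Mirlet7g (chromosome 9, 106178840 to 106178927, in an intron of Wdr82) reached 54222 ± 767 CPM. Mir411, of the Dlk1-Dio3 cluster, was at 62567 ± 3216 CPM. Mir126a (chromosome 2, 26591357 to 26591429, in the endothelial gene Egfl7) was at 61854 ± 8585 CPM. Mir335 (chromosome 6, 30741299 to 30741396, in an intron of the imprinted gene Mest) had 31103 ± 2599 CPM and Mir379 had 31022 ± 875 CPM, a difference within their SDs. Mir23b had 30107 ± 1276 CPM and Mir23a 24365 ± 690 CPM. Mir143, a miRNA abundant in smooth muscle, had 26527 ± 3672 CPM. The rest of the leading 20 were Mirlet7d, Mir99a, Mir322, Mir541, Mir431, Mir382, Mirlet7b and Mir26b, from 20700 ± 174 CPM down to 10403 ± 749 CPM. Of the 20 leading genes of each library, 19 were shared. In both libraries, 169 genes reached 100 CPM. Of the 2202 annotated miRNA genes, 313 were detected with at least 10 counts in both libraries, and 1506 had no count in either. Of the 20 leading genes, 4 shared a hairpin stretch of at least 20 nt with another miRNA gene, namely Mir378a, Mir411, Mir23a and Mir23b.

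**Figure D2:**
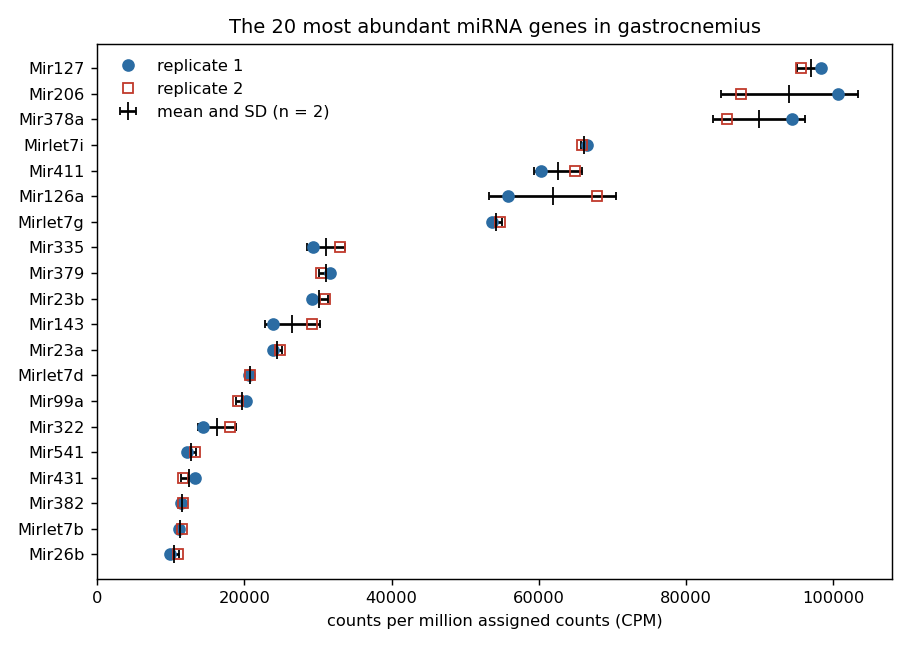
CPM of the 20 most abundant miRNA genes, with each library as a point and the mean and SD (n = 2) as bars. Mir127, Mir206 and Mir378a lie between 85501 and 100599 CPM in both libraries.

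Among the muscle miRNAs, nearly all counts came from Mir206. The 11 listed genes took 9.47% ± 0.92 of the assigned counts, and 99.3% of that was Mir206. Mir499, in an intron of the slow myosin gene Myh7b, had 247 ± 77 CPM. The other members were named after their values were seen. Mir208b, in an intron of the slow myosin gene Myh7, had 43.5 ± 13.1 CPM. Mir208a, the corresponding miRNA of the cardiac myosin locus, had 0 and 2 counts, and Mir1b had 1 and 2 counts. The genes that encode the other classical muscle miRNAs were counted at low levels. Mir1a-2 had 102 ± 14 CPM and Mir1a-1 had 2.61 ± 0.50 CPM. Mir133a-1 had 5.84 ± 1.28 CPM, Mir133a-2 had 1.67 ± 0.12 CPM, and Mir133b, a neighbour of Mir206 in the same long non-coding RNA, had 38.8 ± 6.6 CPM. Mir486 had 212 ± 10 CPM. Of these 11 genes, 6 share at least 20 nt of hairpin with another miRNA gene, among them both copies of Mir1a (28 nt), both copies of Mir133a (31 nt), Mir133b (21 nt) and Mir486 (22 nt). Reads that match several places are in no gene, and the values of these 6 genes are uncertain for that reason. Mir206, Mir499 and Mir208b share no stretch of 14 nt or more of hairpin with another miRNA gene.

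The let-7 family, whose members are known to accumulate as tissues differentiate, was the largest of the 3 listed families let-7, Mir29 and Mir30. Its 12 listed genes were all detected and took 16.2% ± 0.060 of the assigned counts. Mirlet7i contributed 40.7% of that, and Mirlet7g, Mirlet7d (20700 ± 174 CPM) and Mirlet7b (11283 ± 280 CPM) followed. These leading members and Mir98 (3291 ± 45 CPM) share less than 20 nt with another miRNA gene. Mir98 and the genes in the next sentence were named after their values were seen. The genes of the copies let-7a, let-7c and let-7f share 22 to 26 nt and were counted between 145 ± 17 CPM (Mirlet7a-2) and 2955 ± 100 CPM (Mirlet7f-2). These 6 genes can be undercounted for that reason. The share of the family can then be too low, and the part of Mirlet7i in it too high.

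The growth-associated Mir17-92 and paralogous clusters took a small share of the assigned counts, 0.577% ± 0.0049. Mir17 had 2334 ± 81 CPM, Mir93 1261 ± 19 CPM, Mir20a 836 ± 41 CPM and Mir92-1 411 ± 10 CPM, and 11 of 15 members were detected. The Mir30 family took 1.43% ± 0.031, led by Mir30d (6827 ± 330 CPM), Mir30a (5126 ± 74 CPM) and Mir30e (2061 ± 71 CPM), with Mir30b at 117 ± 18 CPM. The Mir29 family, known to target collagen transcripts, took 0.0141% ± 0.0023. Mir29a had 87.0 ± 2.7 CPM, Mir29c 49.7 ± 19.7 CPM, Mir29b-1 2.56 ± 0.27 CPM and Mir29b-2 2.23 ± 1.03 CPM, and all but Mir29a share at least 20 nt with another gene. So do 4 of 15 members of the Mir17-92 and paralogous clusters, Mir92-1 (22 nt) among them, and 2 of 6 of the Mir30 family. Such genes can be undercounted, so the shares of these lists can be too low.

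Imprinted loci, led by the Dlk1-Dio3 cluster, held a large share of the assigned counts. The Dlk1-Dio3 cluster on chromosome 12, expressed from the maternal chromosome, took 28.9% ± 0.19. Its 55 listed genes lie between positions 109563692 and 109747960, and 48 of them were detected. Mir127, Mir411 (109710175 to 109710256), Mir379 (109709060 to 109709125), Mir541 (12713 ± 729 CPM), Mir431 (12532 ± 1138 CPM) and Mir382 (11516 ± 246 CPM) made up 78.6% of the cluster. Mir432, Mir453 and Mir654 had no count in either library, which allows up to 0.75 CPM in replicate 1. The other imprinted loci took 3.63% ± 0.23. Mir335 held 85.6% of that, Mir483, in an intron of the fetal growth factor gene Igf2, had 2853 ± 121 CPM, and Mir298 and Mir296 of the Gnas region had 1925 ± 140 CPM and 407 ± 7 CPM. The X-linked Mir322 cluster, studied for its role in muscle differentiation, took 2.16% ± 0.23, with Mir322 at 16247 ± 2574 CPM, Mir351 at 3874 ± 101 CPM, Mir542 at 830 ± 97 CPM and Mir450b at 314 ± 8 CPM.

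**Figure D3:**
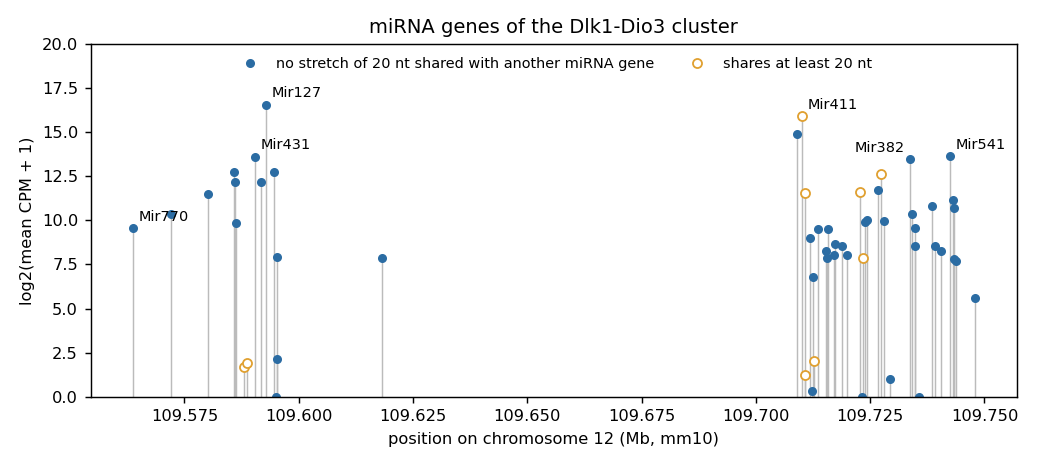
Mean level of the 55 miRNA genes of the Dlk1-Dio3 cluster, as log2(mean CPM + 1), by position on chromosome 12 (mm10), with genes that share at least 20 nt with another miRNA gene as open points. The highest points are Mir127 (96935 CPM) and Mir411 (62567 CPM).

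Among the cell type markers, the endothelial Mir126a and the smooth muscle Mir143 had the highest levels. The endothelial Mir126a took 6.19% ± 0.86 of the assigned counts and the smooth muscle pair Mir143 and Mir145a took 2.71% ± 0.36, with Mir145a at 615 ± 37 CPM. The fibroblast and connective tissue markers took 0.468% ± 0.035, from Mir21a (2722 ± 74 CPM), Mir214 (1204 ± 251 CPM), the cartilage miRNA Mir140 (616 ± 13 CPM) and Mir199b (106 ± 4 CPM). The erythroid pair Mir451a (2736 ± 1647 CPM) and Mir144 (148 ± 56 CPM) took 0.288% ± 0.170, a mean set by replicate 2, since the share was 0.168% in replicate 1 and 0.409% in replicate 2. Mir451a had 1572 CPM in replicate 1 and 3901 CPM in replicate 2. The leukocyte markers took 0.170% ± 0.0025, led by Mir342 (843 ± 13 CPM), Mir146 (424 ± 29 CPM), Mir155 (222 ± 15 CPM) and Mir150 (111 ± 7 CPM). The neural and Schwann cell markers took 0.114% ± 0.0031, from Mir338 (447 ± 37 CPM), Mir128-1 (386 ± 8 CPM), Mir128-2 (133 ± 4 CPM) and Mir132 (101 ± 14 CPM). Mir124a-2, Mir124a-3 and Mir9-2 had no counts, and these are copies of multi-copy miRNAs. At least 20 nt are shared with another miRNA gene by 3 of 6 fibroblast and 10 of 14 neural members. Among these are Mir199b (28 nt), Mir128-1 and Mir128-2 (23 nt each), and the leukocyte Mir146 shares 21 nt. Such genes can be undercounted, so the shares of these lists can be too low.

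The brown adipocyte markers took 0.0651% ± 0.0049, with Mir455 at 589 ± 41 CPM, Mir193b at 56.4 ± 5.8 CPM, Mir365-2 at 3.80 ± 0.63 CPM and Mir365-1 at 2.29 ± 1.00 CPM. Both Mir365 genes share 27 nt with another miRNA gene and can be undercounted. The liver, gut and pancreas markers took 0.0218% ± 0.0115, of which Mir122, the main miRNA of hepatocytes, held 86.0% at 187 ± 120 CPM. Here too the libraries differed, with a list share of 0.0137% and a Mir122 level of 103 CPM in replicate 1 against 0.0299% and 272 CPM in replicate 2. Mir194-2, Mir192 and Mir217 had 9.38 ± 2.65, 8.71 ± 2.54 and 6.10 ± 2.26 CPM, and Mir194-1 had no count. Mir194-2 and Mir194-1 share 22 nt with another miRNA gene. The epithelial markers took 0.00813% ± 0.00133, with Mir203 at 62.6 ± 8.4 CPM, Mir200c at 8.23 ± 0.74 CPM, Mir205 at 6.03 ± 3.50 CPM (8.50 in replicate 1 and 3.56 in replicate 2) and Mir429 at 2.53 ± 0.05 CPM. Of the 11 genes of the embryonic stem cell clusters, none was detected. Mir302b had 1.09 ± 0.13 CPM, and Mir302d, Mir302a and Mir293 had 0.823 ± 0.605, 0.349 ± 0.214 and 0.224 ± 0.037 CPM. Without replicate 1, Mir302d was at 0.395 CPM and Mir302a at 0.198 CPM, from 2 counts and 1 count. Mir290a, Mir291a, Mir294, Mir295, Mir302c and Mir367 had no counts.

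**Figure D4:**
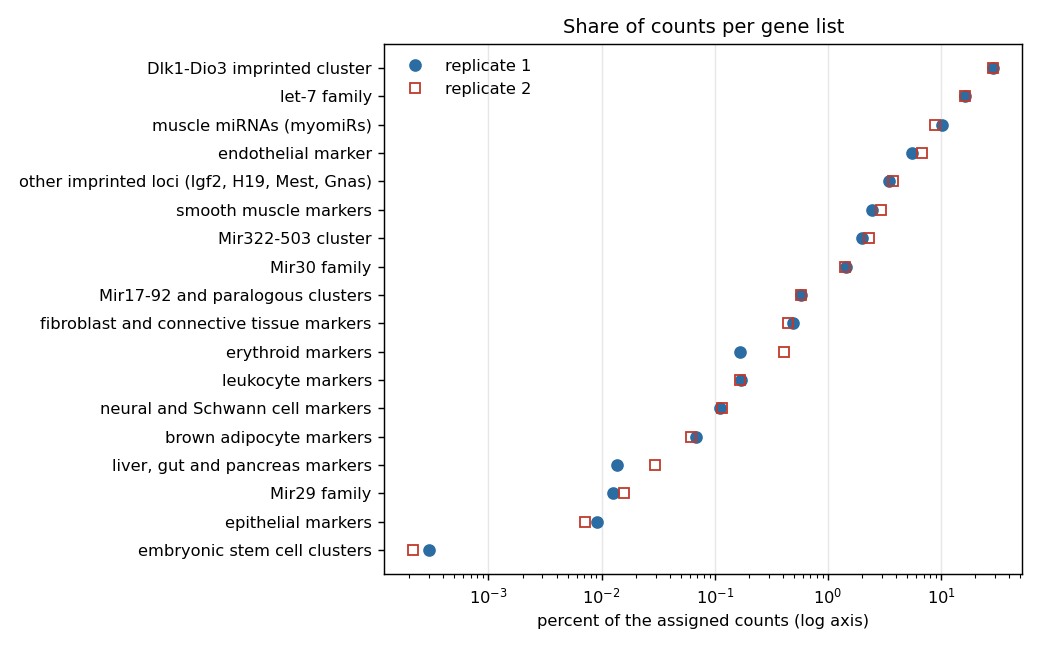
Percent of the assigned counts per gene list (log axis), with each library as a point. Shares run from 28.9% for the Dlk1-Dio3 cluster to under 0.001% for the embryonic stem cell clusters, and the erythroid and the liver, gut and pancreas lists show the widest gaps between the libraries.

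Between the 2 libraries, most miRNA genes lay close to each other, and a small set with the erythroid Mir451a and the hepatocyte Mir122 was higher in replicate 2. Across the 332 genes with a mean of at least 10 counts, which are not independent replicates, Pearson's r was 0.994 and Spearman's rho 0.990. The SD of the log2 ratio was 0.41, a 1.33-fold difference, against 0.21 from counting error alone. The biological coefficient of variation was 0.14. The libraries were not 1 library deposited in duplicate, since the chi-square statistic of their counts was 85.7 per degree of freedom over 331 degrees of freedom. With the exact binomial test, 131 of the 332 genes differed beyond counting error, 90 of them higher and 41 lower in replicate 2. That balance rests on the scaling, since plain library totals gave 62 higher and 79 lower. A difference of at least 1.5-fold was found for 25 genes, 21 higher and 4 lower in replicate 2.

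Among genes with a mean of at least 100 CPM, the differences upward were led by Mir122, which was 2.78-fold higher in replicate 2 (log2 1.48, interval 1.32 to 1.64, exact binomial adjusted p = 1.43e-84). Mir451a was 2.61-fold higher (log2 1.38, interval 1.34 to 1.42) with TMM scaling, as for all ratios here. Its CPM, which use plain library totals, were 1572 in replicate 1 and 3901 in replicate 2 (log2 1.31). Mir144, which neighbours Mir451a, was 1.81-fold higher (log2 0.86, interval 0.69 to 1.03). Mir499 was 1.65-fold higher (log2 0.72, interval 0.60 to 0.85) and Mir708, which shares 23 nt with another miRNA gene, was 1.34-fold higher (log2 0.42). The largest downward log2 ratios were -0.42 for Mir34a, -0.38 for Mir188, -0.36 for Mir214, -0.35 for Mir467d and -0.30 for Mir679. Mir467d belongs to a repeated cluster and shares at least 60 nt with another copy.

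By list, both erythroid markers were higher in replicate 2, as they were when adjusted over the list alone. Of 8 muscle genes tested, 4 were higher (Mir499, Mir208b, Mir1a-2 and Mir486, the last not with plain library totals) and Mir206 was lower by a log2 ratio of -0.13, with 5 differing when adjusted over the list alone. Of 12 let-7 genes, 6 were higher and 1 lower, 7 when adjusted over the list alone, with log2 ratios from -0.16 to 0.30, but plain library totals gave 4 higher and 4 lower. Of 48 Dlk1-Dio3 genes, 18 were higher and 10 lower, 29 when adjusted over the list alone, and plain library totals gave 10 higher and 16 lower. The ratio changed sign between these scalings for 1 of the 7 let-7 genes and 3 of the 28 Dlk1-Dio3 genes that passed with TMM. The smooth muscle Mir143 was higher (log2 0.35), as was the endothelial Mir126a (log2 0.36), while Mir145a gave -0.05 and passed, as lower, only with plain library totals. None of the 4 brown adipocyte markers passed the exact binomial test with TMM, and 1 passed as lower with plain library totals. With the negative binomial exact test of edgeR, which allows for the spread between these libraries, 6 genes passed, all higher in replicate 2. They were Mir92b, Mir137, Mir760, Mir122, Mir451a and Mir7b, of which Mir92b, Mir137, Mir760 and Mir7b are named here after their values were seen. The dispersion of that test was estimated from the same pair of libraries, so its calls are only a ranking of the most divergent genes.

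**Figure D5:**
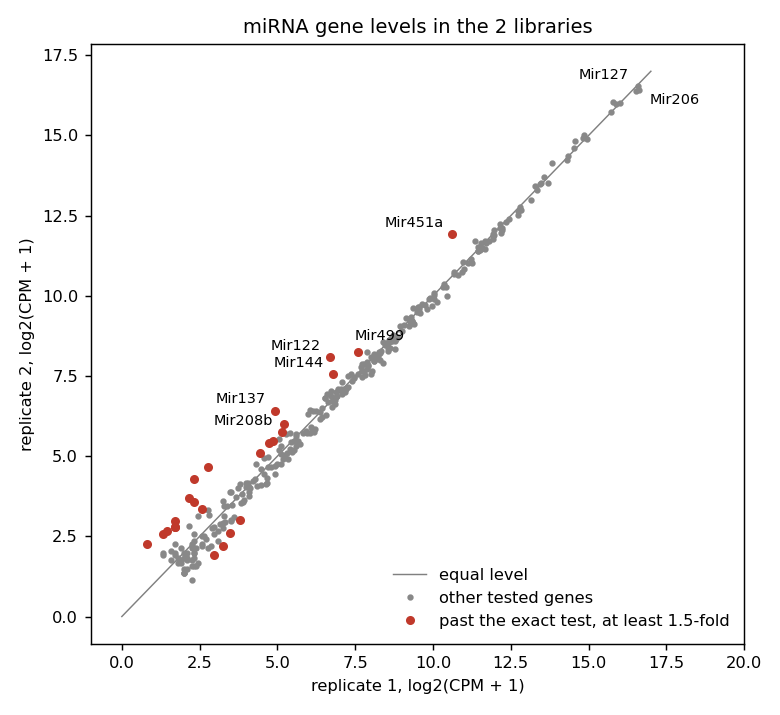
Level of the 332 tested miRNA genes in replicate 1 (x axis) and replicate 2 (y axis), as log2(CPM + 1). Red points are the 25 genes past the exact binomial test with a difference of at least 1.5-fold, and 21 of them lie above the line of equal level.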

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

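The tests in this part were chosen after the results were seen, except that of the leukocyte markers. The first group of values lies in reads that the gene counts do not use. Reads with several genomic matches made up 47.0% of replicate 1 and 48.0% of replicate 2. On the strand opposite to the miRNA genes, 99.995% of the reads in replicate 1 and 99.996% in replicate 2 lay at genes with an annotated miRNA gene on that other strand. At the 2138 genes with no such partner, 35 and 39 reads were found in all in replicates 1 and 2. Of these genes, only 2 (Mir434 and Mirlet7b) had more than the 3 reads that a count of 0 allows in both libraries. The highest value was 9 reads at Mir434 in replicate 1 and 6 reads at Mir122 in replicate 2.

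Some members of multi-copy miRNA families had low counts, such as Mir1a-1 (2.61 ± 0.50 CPM) and Mir133a-2 (1.67 ± 0.12 CPM), which were picked after their values were seen. Mir378a (89927 ± 6259 CPM) did not. Mir411 (62567 ± 3216 CPM), which shares 21 nt with another miRNA gene but is in none of the families compared below, was also high. A candidate explanation is that reads matching several copies are left out. Over 18 families with both kinds of member, the median log2 difference of those sharing at least 20 nt was -1.08, lower in 11. The mean difference was -0.71, and a sign-flip permutation test of that mean gave p = 0.534. The test compares genes whose true levels can differ, so it cannot tell how many reads were left out. The counting drops every read that matches several places, but how far this lowered the counts stays open. Both other stretch lengths were chosen after the result with 20 nt. With at least 22 nt the median was -2.32 over 16 families, lower in 12 (permutation test of the mean, p = 0.0422). With at least 18 nt the median was -0.13 over 15 families (permutation test of the mean, p = 0.551). Loss of reads as ambiguous between overlapping genes is argued against, since 0 reads were ambiguous in the stranded column, and no biological explanation was tested.

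Mir451a, Mir144 and Mir122 were higher in replicate 2. For Mir451a, scaling for the greater depth of that library left the difference in place. Its log2 ratio stayed between 1.31 and 1.38 over TMM, DESeq2 size factors and plain totals, with a lowest lower bound of 1.27. The SD between the libraries was 0.41. Mir451a was picked by its scaled ratio, so this test could hardly have come out otherwise and decides nothing about depth. More whole blood in the tissue might raise erythroid RNA, and it would also raise leukocyte miRNAs. Mir150 and Mir223 had log2 ratios of -0.05 and -0.04 with upper bounds of 0.13 and 0.35, but Mir142 had 0.34 with an upper bound of 0.562, over the bound of 0.5 set beforehand, so the explanation stays open. Their levels were 77.2 CPM for Mir142, 25.5 CPM for Mir223 and 111 CPM for Mir150. Mir144 and Mir122 were not part of these tests. No other biological explanation was tested for these genes.

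Mir208b and Mir499, which lie in introns of slow myosin genes, were both higher in replicate 2, with log2 ratios of 0.69 and 0.72. Scaling for depth left the difference in place. Over the same 3 scalings their ratios stayed between 0.62 and 0.72, beyond the SD of 0.41, with a lowest lower bound of 0.32. Both genes were picked by their scaled ratios, so this too decides nothing about depth. Neither passed the negative binomial test. A larger share of muscle fibre RNA as a whole stays open as a candidate explanation. Mir206 was lower in replicate 2, with an upper bound of -0.125 that covers counting error only, and its ratio lay within that SD. Of the other muscle genes, Mir1a-2 (log2 0.36, interval 0.17 to 0.55) and Mir486 (log2 0.17) were higher, Mir486 not with plain library totals, while Mir133b (log2 -0.28) and Mir133a-1 (log2 -0.38) were lower and Mir1a-1 (log2 0.44) was higher, and these 3 did not pass the exact binomial test. No other biological explanation was tested for Mir208b and Mir499.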

How the results depend on the processing

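The settings were chosen before the data were examined, except the family test and its stretches of 18, 20 and 22 nt given above. Counting genes with at least 1 read in both libraries gave 525 detected genes in place of 313. With all reads as the denominator, the share of the 10 leading genes was 24.9%, that of the muscle miRNAs 3.82% and that of the let-7 family 6.54%, by construction of the larger total. The unstranded column, which has no reads for Mir378a, gave 63.1%, 11.5% and 19.5%. With all reads as the denominator all 18 list shares moved by more than their SD, and in the unstranded column 16 of 18 did. There 64 of 90 named levels moved, where by construction overlapping genes lose their reads and the total is smaller, and Mir126a fell to 0.998 CPM. Pearson's r was 0.993 with a pseudocount of 0.25, 0.996 with 5, 0.996 with no count filter and 0.996 with at least 100 counts, and the SD of the log2 ratio was 0.47, 0.30, 0.25 and 0.27 in that order. The number of genes differing between the libraries fell from 131 to 6 with the negative binomial test, and was 132 with DESeq2 size factors, 141 with plain totals, 116 with no filter and 118 in the unstranded column. The coefficient of variation stayed between 0.134 and 0.142 in its 4 alternatives. Of the 10 genes named for their ratios, none changed direction under the alternatives run on it, and 8 no longer passed under the negative binomial test. With each library alone, 323 to 339 genes were detected, the share of the 10 leading genes was 61.6% to 62.0%, that of the muscle miRNAs 8.82% to 10.1% and that of the let-7 family 16.2% to 16.3%. The erythroid share was 0.168% to 0.409% and the share of the liver, gut and pancreas list 0.0137% to 0.0299%. The cause of the other changes was not tested. At this depth, the 10 counts asked of a detected gene are 2.50 CPM in replicate 1 and 1.98 CPM in replicate 2. No paired analysis was possible because the series has 1 group.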

Other observations

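The sets in this part were chosen after the values were seen. The miRNA genes embedded in the Hox clusters, which mark position along the body, were all 6 detected and took 2.32% ± 0.023 of the assigned counts. Mir10b, in an intron of Hoxd4, had 10240 ± 106 CPM, and Mir196b, at Hoxa9, had 8561 ± 609 CPM. Mir10a had 2960 ± 495 CPM, Mir196a-2 1060 ± 29 CPM, Mir615 343 ± 42 CPM and Mir196a-1 4.87 ± 0.18 CPM. The Mir196a genes share 22 nt with another miRNA gene, so reads may be missing from their counts, which the family test with a median of -1.08 left open.

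The Mir23-27-24 clusters, expressed widely in vessels and muscle, took 5.70% ± 0.18. Within them the levels differed by orders of magnitude, from Mir23b at 30107 ± 1276 CPM and Mir27b at 2147 ± 119 CPM to Mir24-1 at 25.0 ± 6.0 CPM, and the copies of Mir24 share 28 nt. The same held for Mir206 and Mir133b of 1 host RNA, whose counts differed 2312-fold in replicate 1 and 2559-fold in replicate 2. Mir133b shares 21 nt with another miRNA gene and can be undercounted, so these ratios can overstate the difference in level. Mir99a (19683 ± 799 CPM), Mir100 (5511 ± 154 CPM) and Mir99b (4309 ± 504 CPM) were above Mir125a (959 ± 12 CPM) and Mir125b-1 (286 ± 1 CPM). Mir125b-1 shares 24 nt with another miRNA gene. The rodent Sfmbt2 cluster had 119 genes in the tables, of which 6 were detected, with 0.083% ± 0.011 of the counts. These 6 share at least 36 nt with another miRNA gene. The cluster can therefore be undercounted, and a member that was not detected can still be expressed.

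By gene context, intergenic miRNA genes took 41.7% ± 0.53 of the assigned counts and introns of protein-coding genes 28.7% ± 0.26. A gene was called intergenic if no host gene was found on its own strand. Such a gene can still lie within a gene on the opposite strand. Exons of non-coding RNAs took 16.4% ± 0.93, exons of protein-coding genes 8.44% ± 0.72 and introns of non-coding RNAs 4.71% ± 0.063. A gene was called exonic if it overlapped an exon of any transcript of its host, so it can lie in an intron of other transcripts. Mir126a, called exonic in this way, alone took 6.19% of the assigned counts.

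The next genes are those that passed the negative binomial exact test, other than Mir122 and Mir451a, and no enrichment was tested. Mir760 had 16 and 94 counts (log2 2.25). Mir137, of the neural and Schwann cell list, had 118 and 429 counts (log2 1.59), Mir92b 23 and 123 counts (log2 2.12) and Mir7b 14 and 61 counts (log2 1.82). Mir760, Mir92b and Mir7b are in none of the lists. Of the 8 neural and Schwann cell genes tested, 2 were higher and 0 lower by the exact binomial test with TMM, and plain library totals gave 2 higher and 1 lower (Mir338). Mir212 had the lowest ratio (log2 -1.01) and did not pass. No explanation was tested for these.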
